A study of Oryza sativa with 12 samples.

How the data were processed

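Biotin-labelled RNA of 12 samples, shoots and leaves of rice seedlings, had been hybridised to 1 GeneChip array each. A day of 14 h of light and 10 h of dark is recorded for the samples taken after cold and not for those before it. The values are probe set intensity values as deposited by the authors, on a linear scale. The summary and normalization method was not given in the sources used here. Intensities ran from 2.9 to 23434.8, and array medians from 34.6 to 37.15. The number of arrays limits the precision.

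Of 57381 probe sets, 123 control probe sets were left out and kept only as checks. An annotation table paired 22436 probe sets with 1 gene, 95 with several and 34727 with none, and 3190 probe sets belong to one of 2455 genes with a published name. Intensities were taken as log2(value + 16), a scale on which the change of dim probe sets is understated. Because array quartiles differed by up to 0.238 on this scale, above a limit of 0.2, arrays were quantile normalized. Probe sets with a mean at or above the 40th percentile were kept, 34355 in all.

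Models were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with trend), and a probe set was called at a Benjamini-Hochberg adjusted p below 0.05. Overexpression lines were compared with the ZH11 control, and mutants with the Huayang wild type, in a model of 8 group means with 4 residual degrees of freedom. In it the single control and wild type arrays are assumed to vary like the other groups. Contrasts were taken before cold, at 6 h, as the mean of both times, and as the interaction with cold. The cold response was fitted in each cultivar (3 arrays against 3), in all lines with cultivar as a term (6 against 6), and as an interaction with cultivar. The sampled line gives a pairing, since each line was sampled at both times. Across probe sets the deviations of a line's pair of arrays from their group means correlated at 0.517 in the overexpression lines and 0.429 in the mutants, 2 lines each. Fits with line as a random block (correlation 0.334) or, for the effect of cold, as a fixed block are given where they end or add a call of a gene given by name or move a count given in the text by more than 1.5 times. The limit of 73.9 for dim readings, the highest of the dim marker probe sets, was chosen after the data were examined.

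Comparisons, thresholds, alternatives and the rule for naming genes were set before the data were examined. The rule takes the 10 largest increases and decreases per main contrast among called probe sets of 1 gene that moved the same way in every line and time, and the 5 largest each way before cold, at 6 h and in the interactions, with values only where none passed. The rule spoke of genes with a description; the annotation holds none, so it was read as genes with a published name. Of lists, the 3 largest called members are named, or the 2 largest as values. OsMYB30 and the beta-amylases were to be given always but are paired with no probe set.

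The 23 gene lists cover other starch breakdown, starch synthesis, trehalose synthesis, sugar transport and sucrose, DREB1 regulators, dehydrins and LEA proteins, TIFY repressors, jasmonate synthesis, phenylpropanoids and lignin, light harvesting, the clock, abscisic acid, heat shock, peroxide and glutathione enzymes, defence proteins, WRKY factors, ribosomal proteins, expansins, dividing cells, secondary wall, root, epidermis, and housekeeping. Sugar transport and sucrose was not a planned list, a planned list of class III peroxidases was not tested, and trehalose and raffinose became trehalose alone. The other themes were fixed before the data were examined, as keywords and locus IDs. The annotation has neither, so the members were rewritten as published names before any model was fitted. Each gene entered with its brightest probe set. Lists were tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry, adjusted over the 23 lists. Neither of fry's tests compares a list with other genes.

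Alternatives were the values as deposited, median centring, no filter or a 60th percentile filter, pseudocounts of 1 and 64, averaged probe sets, eBayes without trend or with robust, a 2-fold minimum, line as a block, only arrays of the same cultivar, the model of 8 group means for cold, other set tests, other probe sets of a gene, and each array left out in turn. On simulated data with 50 probe sets changed per size, limma recovered 68% of 2-fold changes before cold in a comparison of 2 arrays with 1, 90% for the mean of both times in the overexpression lines, 88% in the mutants, 48% for the genotype interaction, 86% for cold in ZH11, 100% in all lines and 88% for the cultivar interaction. It called 4 to 10 unchanged probe sets in each. In a simulated list test camera called the shifted list and 0 of 22 others. The simulated noise was independent between arrays and between genes. These counts therefore do not cover the correlation of a line's arrays or of genes within a list.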

Results

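RNA from shoots and leaves of rice seedlings at the 4-leaf stage was measured on 12 GeneChip arrays, 1 array per sample. In the ZH11 cultivar, 2 lines that overexpress OsMYB30, a MYB transcription factor, were set beside 1 control line. In the Huayang cultivar, 2 lines homozygous for an osmyb30 mutation were set beside 1 wild type line. Each of these 6 lines was sampled before cold and after 6 h at 4 °C, so each overexpression and mutant group held 2 arrays and each control and wild type group held 1. The number of arrays limits the precision. Median deposited intensities lay between 34.6 and 37.15 on the 12 arrays. Changes below are differences of log2(intensity + 16), which understates the change of dim genes, and errors are standard errors (SE) from limma.

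The arrays were ordered first by cold and then by cultivar. The first principal component held 45.5% of the variance and parted the times, and the second held 33.0% and parted the cultivars. The third held 7.41% and set the ZH11 control arrays, at -30.70 and -25.47, apart from the overexpression arrays, at 1.88 to 28.24. Most marker probe sets, which detect reporter and selection genes, were dim, but 2 were bright in part of the plants. RPTR-Os-K01193-1_at read 11860.8 to 12539.4 in the overexpression lines, 13835.2 to 17781.9 in the mutants, at most 64.3 in the ZH11 control, and 2658.5 and 3821.8 in the wild type. RPTR-Os-A00196-1_s_at read 7940.3 to 10805.7 in the overexpression lines and at most 113.5 elsewhere. No probe set is paired with OsMYB30 in the annotation, so its transcript was not analysed here, nor were the beta-amylases. The other marker probe sets read up to 73.9. Where a group in a called change averaged at or below that level, the size is not established, and the change is given as at least its value with readings below 73.9 set to 73.9, or without a size where little is left.

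**Figure D1:**
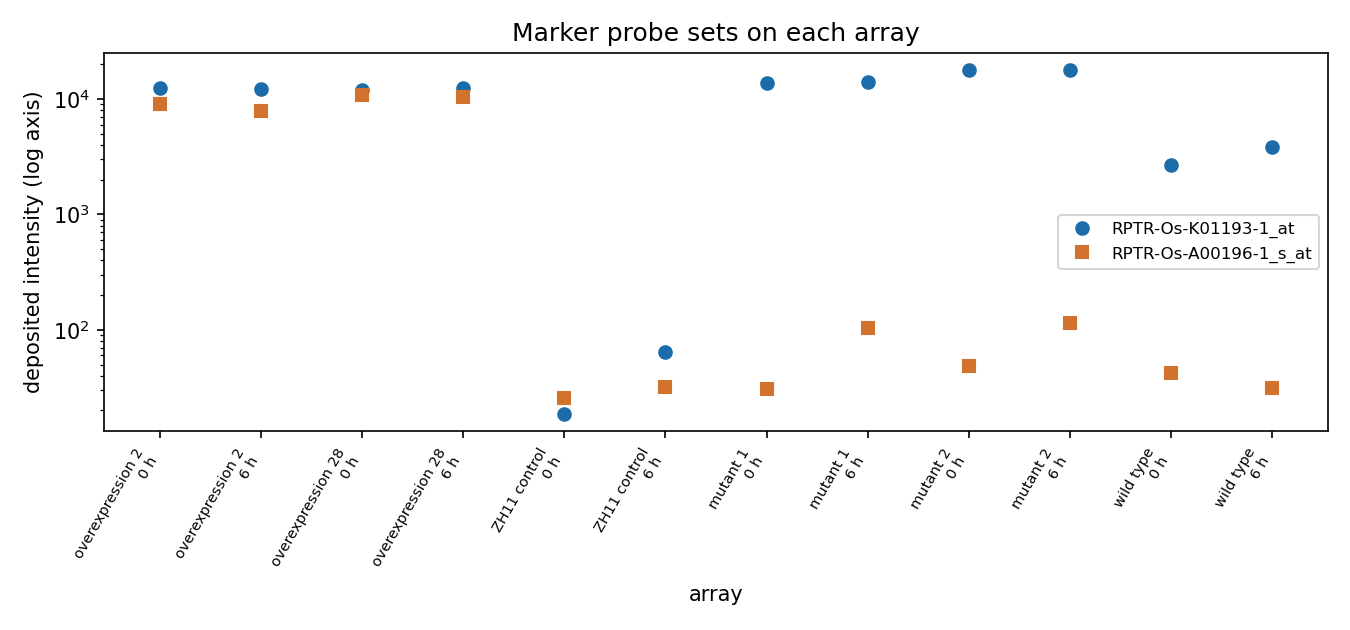
Deposited intensity (log axis) of the 2 bright marker probe sets on each of the 12 arrays, 1 point per array and probe set. The overexpression lines are bright for both, the mutants for the first only, and the wild type reads 2658.5 and 3821.8 for the first.

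The first comparison asks which genes differ between the overexpression lines and the ZH11 control. As a mean of both times (4 arrays against 2), phenylpropanoid enzymes were among the genes that were higher. The transcript of 4CL5, a 4-coumarate-CoA ligase, was 3.99-fold higher in the overexpression lines (log2 change 2.00, SE 0.11, adjusted p = 0.000106), and that of PAL06, a phenylalanine ammonia-lyase that opens the pathway, was 3.06-fold higher (log2 change 1.61, SE 0.11, adjusted p = 0.000418). EIL1B, an EIN3-like factor of ethylene signalling, was higher by 1.25 (SE 0.17) and the glutathione transferase gene GSTF1 by 1.11 (SE 0.14) and TGAL8 passed the test as well. TGAL8, a bZIP factor gene, read between 9.7 and 64.2 on all arrays, within the range of the dim marker probe sets (up to 73.9), so the size of its difference is not established. The metallothionein gene MT2C was lower, with a log2 change of -1.10 (SE 0.05, adjusted p = 3.89e-05). So were the manganese and cadmium transporter gene NRAMP5 at -0.70, the B-type cyclin gene CYCB1-1 at -0.56 or beyond, ILL6, which encodes an auxin-conjugate hydrolase-like protein, at -0.59 or beyond, the mini zinc finger gene MIF4 at -0.64, the mannan synthase-like gene CSLA1 at -0.64 and RGP3 at -0.60. A second probe set of RGP3 gave 0.21, in the opposite direction.

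A further 8 of the 20 named genes passed the test only without line as a block. They are LEA19 (at least 2.66), whose product is a late embryogenesis abundant protein, the cytochrome P450 gene CYP71Z7 (at least 1.47), the chitinase gene Cht8 (1.34, SE 0.30), the probenazole-inducible defence gene PBZ1 (1.16, SE 0.24), the glutathione transferase gene GSTU1 (1.12, SE 0.17), the phosphate transporter gene PHT1-2 (-0.81, SE 0.14), the chitinase gene Cht10 (-0.72, SE 0.16) and AP25 (-0.64, SE 0.14). With line as a block their adjusted p values in limma ranged from 0.0541 to 0.101. Genes without a published name moved further. LOC4332568 was higher by 4.16 (SE 0.13) and LOC4340800 by 3.70 (SE 0.10), and LOC4336552 was lower, but read within the dim range in the overexpression lines. These genes were singled out after their values were seen and kept their calls with line as a block. For LOC4336552 the control stood apart, at 6.92 and 6.80 on the log2 scale, from the overexpression lines (5.03 to 5.24) and the Huayang arrays (4.89 to 5.26). For LOC4340800 the control (7.52 and 7.20) lay below the Huayang arrays (9.34 to 10.06), and the overexpression lines (10.94 to 11.17) lay above them. For LOC4332568 the control (9.32 and 9.31) lay within the range of the Huayang arrays (9.26 to 10.05).

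**Figure D2:**
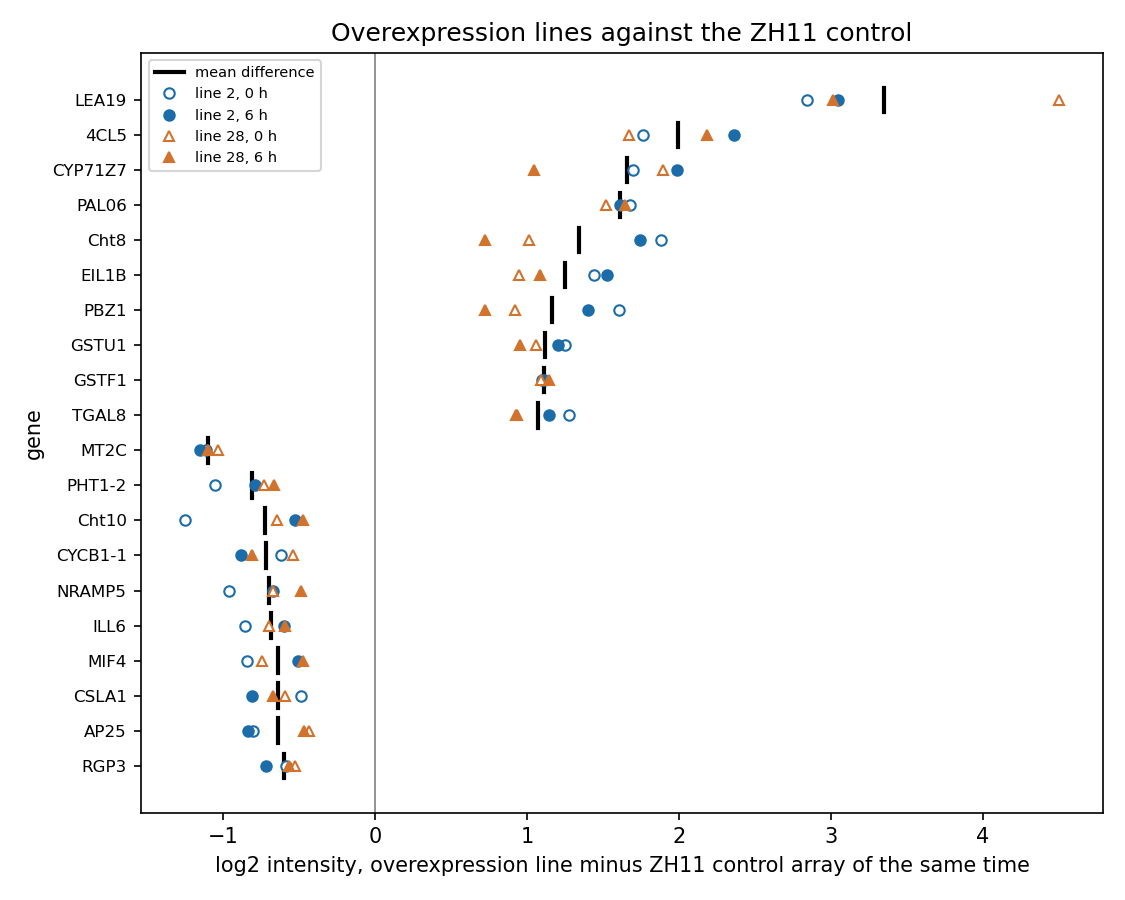
Log2 difference between each overexpression line and the ZH11 control at each time for the 20 named genes, 1 point per line and time, with a bar at the mean. The values of 4CL5 average 2.00 and those of MT2C average -1.10.

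Gene lists point to the same pathway. Of 18 measured phenylpropanoid and lignin genes, 8 were higher and 0 lower over all probe sets, against 8 higher and 2 lower adjusted over the list alone. Beside 4CL5 and PAL06 the higher members were 4CL3 (0.66), the cinnamyl alcohol dehydrogenase gene CAD2 (0.58), the O-methyltransferase gene ROMT-15 (0.55), the hydroxycinnamoyl transferase genes HCT1 (0.52) and HCT2 (0.33), and PAL (0.23). Camera gave the list an adjusted p of 0.00547 and fry one of 0.00104; adjusted p = 0.25 with an estimated correlation in camera. Of 21 peroxide and glutathione enzyme genes, 4 were higher (GSTU1, GSTF1, the ascorbate peroxidase gene APX7 at 0.86 and GSTF2 at 0.32), against 5 higher and 2 lower adjusted over the list alone. Its camera adjusted p was 0.0381, and adjusted p = 0.35 with an estimated correlation. Among 10 defence protein genes, Cht8 and PBZ1 were higher and Cht10 lower, against 6 higher and 1 lower adjusted over the list alone, with a median of 0.65 (camera adjusted p = 0.0278, and adjusted p = 0.398 with an estimated correlation). On the values as deposited neither the peroxide and glutathione list nor the defence list passed camera (adjusted p = 0.0925 and 0.1), while the phenylpropanoid list did (adjusted p = 0.0108). Fitted with line as a block, limma called 7 higher in the phenylpropanoid list (all but PAL), 3 in the peroxide and glutathione list (all but GSTU1) and 0 in the defence list.

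Lists of expansins, dividing cells, housekeeping genes and epidermis lay on the lower side. None of 22 expansin genes, whose products loosen cell walls, passed over all probe sets (1 higher and 1 lower adjusted over the list alone), and the list's median was -0.19 (camera adjusted p = 0.00547, and adjusted p = 0.398 with an estimated correlation). Of 16 genes of dividing cells, 0 were called by limma over all probe sets and 5 were lower adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.00334, and adjusted p = 0.356 with an estimated correlation). The minichromosome maintenance genes MCM4 and MCM5, which act in DNA replication, had values of -0.41 each, in the dim range. Of 20 housekeeping genes the actin genes ACT2 (-0.51) and ACT3 (-0.42) were lower, against 1 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.00063, and adjusted p = 0.25 with an estimated correlation). Epidermis and cuticle genes had a median of -0.05 with none of 11 called and 3 lower adjusted over the list alone (camera adjusted p = 0.0278, and adjusted p = 0.35 with an estimated correlation). DREB1G, a cold-response regulator gene, was higher by at least 0.37, a difference that passed without line as a block and not with it (adjusted p = 0.0644 in limma), 1 of 5 DREB1 genes, and their list had a camera adjusted p of 0.116.

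Over 34355 probe sets, limma called 746 higher and 649 lower in the overexpression lines as a mean of both times, 1395 in all. With line as a block it called 425, 273 higher and 152 lower, all among the 1395. The direction of the calls moved with scaling, to 1030 higher and 467 lower on the values as deposited and 1431 higher and 358 lower with arrays centred on their medians. Leaving out line 2 before cold gave 473 calls, leaving it out at 6 h gave 309, and leaving out line 28 at 6 h gave 783. Those 3 runs ended 8, 9 and 3 of the 20 named calls, with adjusted p values in limma of 0.0513 to 0.139, and 4CL5, PAL06 and MT2C were not among them.

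At each time alone the leading genes were again 4CL5, PAL06 and MT2C. Before cold (2 arrays against 1), 4CL5 was higher by 1.72 (SE 0.15), PAL06 by 1.60 (SE 0.16), APX7 by 0.98 (SE 0.12), the shikimate kinase gene SK2 by 0.94 (SE 0.15) and the ABC transporter gene ABCG45 by at least 0.63. MT2C (-1.08), the COBRA-like gene BC1L9 (-0.80), MIF4 (-0.79), ILL6 (-0.78) and the phosphate transporter gene PHT1-8 (-0.60) were lower. Second probe sets of BC1L9 (-0.24) and PHT1-8 (-0.60) were not called. Phenylpropanoid genes had 3 of 18 higher over all probe sets, and 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0154, and adjusted p = 0.26 with an estimated correlation), and on the values as deposited the list just missed the threshold in camera, at 0.05005. Expansin, dividing cell, epidermis and housekeeping lists also passed camera on the lower side, and none of them did with an estimated correlation, where adjusted p = 0.26 or more for each. In all, 132 probe sets were higher and 64 lower, against 167 and 98 with line as a block. The split was 265 and 55 on the values as deposited and 559 and 62 with median centring, which moved the median of all probe sets to 0.10. BC1L9, MIF4, ILL6 and PHT1-8 lost their call under another scaling, as Cht10 did for the mean of both times and, with median centring, CSLA1 at 6 h. Without line 2 limma called 60 and without line 28 it called 123; 7 of the 10 named genes lost their call in at least 1 of these runs (adjusted p 0.0608 to 0.171), all but 4CL5, PAL06 and MT2C.

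After 6 h of cold, 4CL5 was higher by 2.27 (SE 0.15) and PAL06 by 1.63 (SE 0.16). CYP71P1, whose enzyme makes serotonin from tryptamine, was higher by 1.00 (SE 0.12), the S-adenosylmethionine synthetase gene SAM2 by 0.89 (SE 0.10) and RAN1 by 0.87 (SE 0.11). MT2C (-1.13), CSLA1 (-0.74), the silicon transporter gene Lsi6 (-0.67) and RGP3 (-0.64, and 0.21 for its second probe set) were lower. Phenylpropanoid genes had 2 of 18 higher, and 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000239, and adjusted p = 0.203 with an estimated correlation). Peroxide and glutathione, defence, expansin, dividing cell, secondary wall and housekeeping lists passed camera as well, the first pair higher and the others lower, and none did with an estimated correlation, where adjusted p = 0.271 or more for each. In fry with line as a block the peroxide and glutathione list also passed (adjusted p = 0.0402, and 0.0639 without the block). On the values as deposited trehalose synthesis and ribosomal protein lists passed camera too, on the lower side (adjusted p = 0.0402 and 0.0388). In all, 79 probe sets were higher and 28 lower. Without line 2 limma called 40 and without line 28 it called 35; 7 of the 9 named genes, PAL06 among them, lost their call in at least 1 of these runs (adjusted p 0.0627 to 0.231), and 4CL5 and MT2C kept theirs.

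As a description without a test, both overexpression lines differed at least 2-fold from the control in 1 direction for 74 probe sets higher and 28 lower before cold, and for 72 higher and 28 lower at 6 h. Both lines lay on the same side of the control for 80.8% of probe sets before cold and 73.9% at 6 h, where chance gives 66.7% because they share the control array.

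The second comparison asks which genes differ between the mutants and the Huayang wild type. Few were called. With 1 wild type array at each time, that does not show that few differ. The wild type also read 2658.5 and 3821.8 for a marker probe set that was bright in the mutants. Whether its samples held RNA of the mutants stays open below. Such RNA would make the differences between mutants and wild type smaller, also those in the response to cold. After 6 h of cold (2 arrays against 1), NAAT1, which encodes a nicotianamine aminotransferase used to make iron-chelating phytosiderophores, was lower in the mutants by a log2 change of -1.13 (SE 0.11, adjusted p = 0.0416), and it was the only gene with a published name among the calls. Its call was lost on the values as deposited (-1.09, adjusted p = 0.0719 in limma), with median centring (-1.08, 0.0656), and, at an unchanged -1.13, with the 60th percentile filter (0.0546), without trend (0.0687) and with arrays of Huayang alone (0.0677). LOC4340783 was also lower at 6 h (-2.17, SE 0.13), as were LOC4352132 (-1.37, SE 0.12) and LOC4348874 (-1.30, SE 0.12). As a mean of both times these 3 had changes of -1.17, -1.06 and -0.81, and LOC4339518 (0.55, SE 0.05) and LOC4333966 (0.42, SE 0.04) were higher. Among probe sets without a gene in the annotation, 3 were higher in the mutants, the first by at least 2.19, the second by 2.79 (SE 0.30) and the last without an established size. With the block the mean lost the calls of LOC4348874 (adjusted p = 0.143 in limma), LOC4339518 and LOC4333966 (0.055 each) and the second and the last of these probe sets (0.0758 and 0.0683), while LOC4340783 and LOC4352132 kept theirs (0.0499 and 0.035). For the first probe set the wild type read 5.52 and 5.60 on the log2 scale, and the 4 mutant arrays lay between 8.21 and 8.98, near the ZH11 control at 8.89 and 8.83. The marker probe set RPTR-Os-K01193-1_at was higher by 2.28 (SE 0.11) as a mean of both times and by 2.55 before cold, where it was the only call. The genes and probe sets of this paragraph other than NAAT1 were chosen after their values were seen, since no other named gene passed.

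In limma 1 probe set was called before cold, 7 at 6 h (3 higher and 4 lower) and 9 as a mean of both times (6 higher and 3 lower). An unadjusted p below 0.05 in limma was reached by 1736, 3271 and 4310 of 34355 probe sets. The first of these is close to the share of 0.05 that chance gives. With line as a block limma called 2 before cold and 4 for the mean (2 higher and 2 lower), and at 6 h either other scaling gave 4 higher and 3 lower. Left-out arrays moved the numbers of calls. Without mutant line 1 at 6 h limma called 84 at 6 h and 30 for the mean, without that line before cold it called 3 before cold and 4 for the mean, and without mutant line 2 before cold it called 3; NAAT1 lost its call without mutant line 2 at 6 h (adjusted p = 0.134). Of the gene lists, the 6 WRKY genes before cold passed camera, on the lower side with a median of -0.32, 0 called over all probe sets and 0 adjusted over the list alone (adjusted p = 0.0388; adjusted p = 0.803 with an estimated correlation). The largest values among them were -0.74 for WRKY76 and -0.56 for WRKY8. Phenylpropanoid genes as a mean of both times had 0 of 18 called, 0 adjusted over the list alone, and a median of -0.05 (camera adjusted p = 0.068). On the values as deposited that list passed camera on the lower side, before cold (adjusted p = 0.0168) and as a mean of both times (0.0123). So did, on the lower side, the TIFY and WRKY lists at both of these, ribosomal protein, expansin and housekeeping lists before cold, and light harvesting for the mean; at 6 h the DREB1, TIFY and light harvesting lists passed lower and ribosomal proteins higher. An estimated correlation was not run on these values. Both mutants differed at least 2-fold from the wild type in 1 direction for 5 probe sets higher and 0 lower before cold and for 12 higher and 50 lower at 6 h, a count without a test. Both mutants lay on the same side of the wild type for 70.8% of probe sets before cold and 67.9% at 6 h, where chance gives 66.7% because they share the wild type array.

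Whether the genotype changed the response to cold was tested as an interaction, and limma called 0 probe sets for the overexpression lines (1401 at an unadjusted p below 0.05) and 0 for the mutants (1006). Both unadjusted counts lie below the share of 0.05 that chance gives over 34355 probe sets. The named values for the overexpression lines were -1.54 (SE 0.52) for WRKY76, -1.18 (SE 0.24) for DXPS and -1.16 (SE 0.41) for the laccase gene LAC19. For the mutants they were -4.63 (SE 1.28) for NAS1 and -3.77 (SE 0.98) for NAS2, which encode nicotianamine synthases, -2.03 (SE 0.68) for the late embryogenesis gene Emp1, -1.96 (SE 0.73) for PM1, -1.82 (SE 0.70) for KS10 and 1.15 (SE 0.37) for OsCel9E. Of these, DXPS, LAC19, NAS1, Emp1, KS10 and OsCel9E had a group in the dim range, so those sizes are not established; with readings below 73.9 set to 73.9 the value of NAS1 was -4.09 and that of LAC19 -0.04. With line as a block limma called 1 probe set in each. In the mutants it was NAS1 (adjusted p = 0.0152), and in the overexpression lines it was RPTR-Os-K01193-1_at (adjusted p = 0.0459), which is no measured change of the marker: the overexpression lines read 13.57 and 13.60 on the log2 scale, and the control, at most 64.3, lay in the range of the dim marker probe sets, up to 73.9. Without mutant line 1 at 6 h limma called 1 probe set for the mutants. The iron-chelator genes of the figure were chosen after their values were seen: NAS1 went from 11.43 and 10.18 to 6.24 and 5.67, within the dim range, in the mutant lines and changed by -0.22 in the wild type, NAS2 by -4.62 and -3.26 against -0.17, and NAAT1 by -1.08 and -1.15 against -0.09. Of 4 other iron genes looked at, NAS3, another nicotianamine synthase gene, changed by 0.55 and 0.42 against 0.31, and the interaction values were 0.17 for NAS3, -0.17 for YSL15, -0.43 for IRT1 and -0.60 for BHLH063. YSL15 lay between 5.67 and 6.16 on all arrays, in the dim range, so its small value does not show that it was unchanged.

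**Figure D3:**
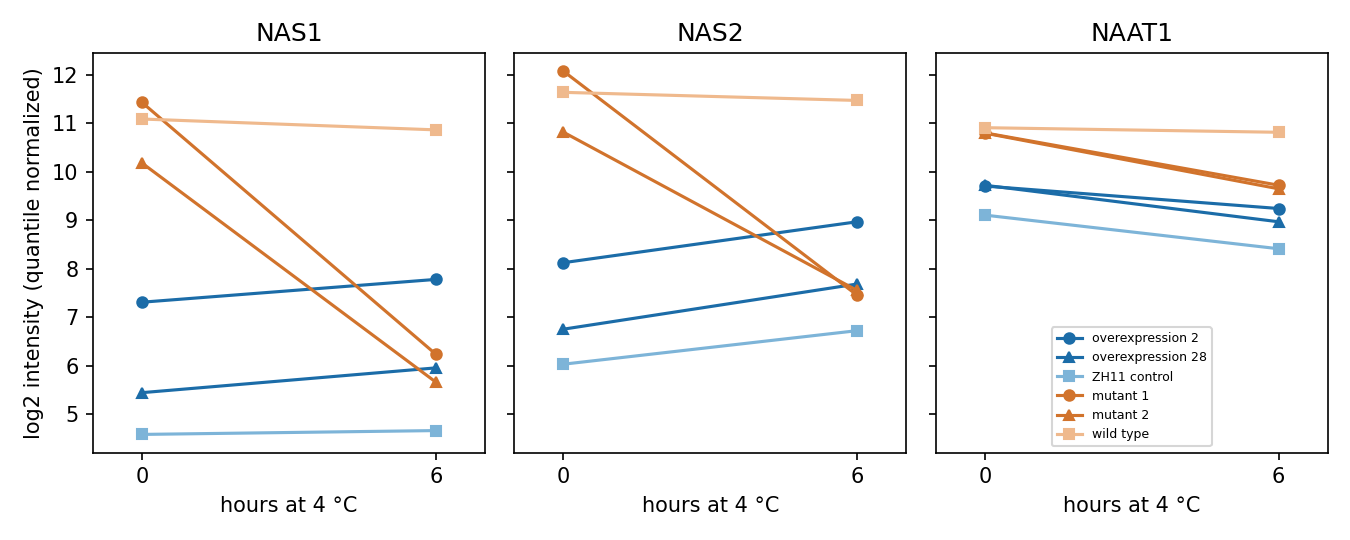
Log2 values of NAS1, NAS2 and NAAT1 before and after 6 h of cold, 1 line per plant line. NAS1 stood at 11.09 and 10.86 in the wild type, and at 11.43 and 6.24 in mutant line 1, the latter within the range of the dim marker probe sets.

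Ribosomal protein genes passed camera in the mutant interaction, with a median of 0.12, 0 of 20 called and 0 adjusted over the list alone (adjusted p = 0.00222, 0.0198 with line as a block; adjusted p = 0.979 with an estimated correlation).

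The design also sets a gain of OsMYB30 against a loss. LOC4352132 was higher in the overexpression lines (1.102, SE 0.09) and lower in the mutants (-1.06, SE 0.09) as a mean of both times, and likewise at 6 h (1.12 and -1.37). Before cold and at 6 h its log2 level averaged 8.20 and 8.10 in the overexpression lines and 8.23 and 7.81 in the mutants. The control read 7.12 and 6.98 and the wild type 8.97 and 9.19. The opposite calls thus rest on the single control and wild type lines, which are of different cultivars. LOC4333966 was lower in the overexpression lines (-0.20, SE 0.04) and higher in the mutants (0.42, SE 0.04), a call lost there with line as a block. The third shared call, RPTR-Os-K01193-1_at, was higher in both. Independent lists of these sizes would share 0.0651 probe sets higher in the overexpression lines and lower in the mutants. They would share 0.113 in the other opposite direction and 0.13 higher in both. The 2 lists are not independent, since both contrasts came from 1 fit and each probe set had the same SE in both. A probe set with a small SE is more easily called in both, so these numbers do not give the overlap that chance would produce. Across probe sets, which are not independent replicates, the changes correlated at r = 0.10 for the mean of both times, 0.29 before cold and -0.12 at 6 h; the contrasts share no array.

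The third comparison asks what 6 h at 4 °C changed in all lines (6 arrays against 6). Among genes with a published name, regulators of the cold and jasmonate responses rose most, and LOC4347266, singled out after its value was seen, rose by at least 5.28. DREB1B and DREB1A, transcription factors that switch on cold-response genes, rose 92.2-fold (log2 change 6.53, SE 0.09, adjusted p = 5.79e-14, from a mean intensity of 79.9, close to the dim range) and by a log2 change of at least 6.07, and DREB1G rose by at least 4.04. The jasmonate signalling repressor genes TIFY11E, TIFY11A and TIFY11B rose by at least 5.77, by 5.39 (SE 0.26) and by 4.10 (SE 0.06). ABA8OX1, whose enzyme breaks down abscisic acid, rose by 5.28 (SE 0.08), MYB2 by 4.63 (SE 0.07), LTR1 by 4.30 (SE 0.10) and the calmodulin-like gene CML15 by 3.99 (SE 0.11). The beta-expansin gene EXPB7 fell by 2.16 (SE 0.11), TDL1B by at least 1.38, the calcium-signalling kinase genes CIPK5 and CIPK6 by 1.94 (SE 0.14) and 1.71 (SE 0.11), MIF3 by 1.69 (SE 0.15), the receptor kinase gene CR4 by at least 1.47, the homeobox gene HOX4 by 1.46 (SE 0.08), EXPA7 by 1.44 (SE 0.32) and OsCASPL2B1 by at least 1.17, and bHLH081 fell without an established size. A second probe set of EXPA7 gave 0.16, and the other probe sets of OsCASPL2B1 gave -0.31 and -0.21. The naming rule took only genes that moved in 1 direction in 6 of 6 lines.

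**Figure D4:**
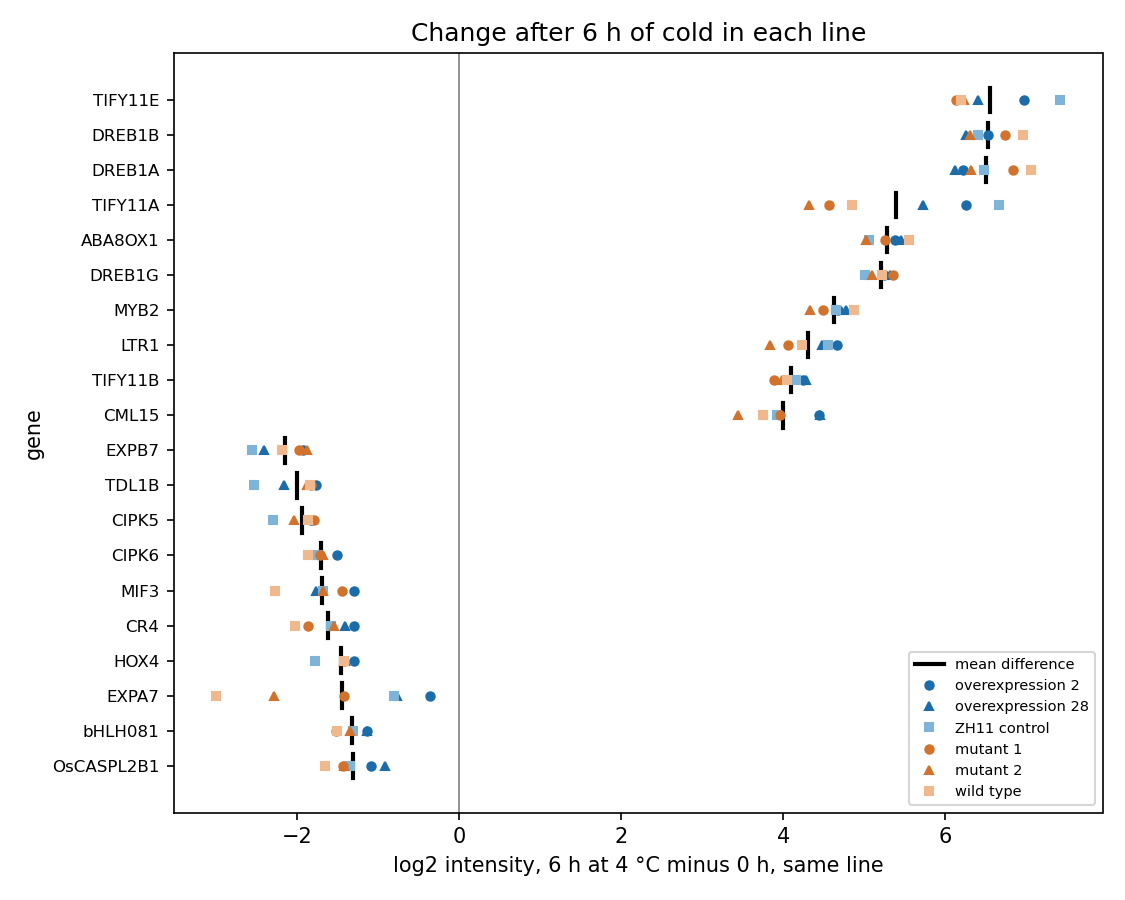
Log2 change after 6 h at 4 °C in each of the 6 lines for the 20 named genes, 1 point per line, with a bar at the mean difference. DREB1B lies near 6.53 in every line, while TIFY11A is higher in the ZH11 lines than in the Huayang lines.

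All 5 measured DREB1 genes rose, DREB1E by at least 0.92 and DREB1C in the dim range (5 adjusted over the list alone; camera adjusted p = 1.19e-07, and adjusted p = 0.04 with an estimated correlation). Of 13 TIFY genes 6 rose and 2 fell, the same counts adjusted over the list alone, and TIFY10B fell by 0.30 (camera adjusted p = 0.0024; adjusted p = 0.605 with an estimated correlation). Jasmonate synthesis genes had 3 of 9 higher, led by the allene oxide synthase gene AOS2 (1.49), and 2 lower. The trehalose phosphatase genes TPP1 and TPP7 rose by 3.76 and 2.05 and TPP10 fell in the dim range, among 5 measured (camera adjusted p = 0.108). Of 6 WRKY genes, WRKY71 (3.37), WRKY8 (3.06) and WRKY76 (2.14) rose, and WRKY51 fell by 1.17 and WRKY9 by 0.26. Of 22 expansin genes 13 fell and 1 rose, against 14 and 2 adjusted over the list alone, with EXPA5 and EXPB11 at -1.26 and -1.23. The camera adjusted p of that list was 0.0617, and 0.04 with line as a block; adjusted p = 0.698 with an estimated correlation, without the block.

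Of 21 abscisic acid genes 4 rose and 8 fell (4 and 10 adjusted over the list alone); SAPK2, a kinase gene of the pathway, rose by 0.69 and the phosphatase gene PP2C68 fell by at least 0.89, and the list's median of -0.12 and mean of 0.14 differ in sign. Of 26 sugar transport and sucrose genes the sugar exporter genes SWEET1B, SWEET2B and SWEET16 fell by 0.83, 0.73 and 0.70 among 7 that fell, and the sucrose transporter gene SUT4 rose by 0.46. Among 7 clock genes, PCL1 rose by 1.73 and PRR95 by 0.11, and CCA1 fell by 0.19 and PRR73 by 0.16. Heat shock genes had 2 of 20 higher and 6 lower, with HSP17.9B down by 0.83. Phenylpropanoid genes had 4 of 18 higher and 2 lower, with PAL06 at 1.56 and CAD8A at -0.48 or beyond, and a median of -0.03 against a mean of 0.08. Of 10 defence genes Cht6 rose by 1.38 and Cht10 fell by 0.81. Starch synthesis had 1 higher of 8 (SSII-2 at 0.12), other starch breakdown 1 of 5 (GWD3 at 0.21), dehydrin and LEA genes 1 of 8 (Dip1 at 0.97, with a list median of -0.10 against an upward camera direction), peroxide and glutathione enzymes 1 of 21 (APX8 at 0.20), and light harvesting genes 1 lower of 11 (PSAG at -0.18).

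Ribosomal protein genes had 7 of 20 lower, led by RPL18 (-0.25), and housekeeping genes 7 of 20 lower, led by TUBB1 (-0.28). Dividing cell genes had 1 higher, CDKB2-1 (at least 0.45), and 5 histone genes lower of 16, led by H2B.6 (-0.65). Secondary wall genes had 1 higher and 5 lower of 10, led by the laccase gene LAC19. Root genes had 2 lower of 5, led by the ammonium transporter gene OsAMT1;2, and epidermis genes 1 higher and 6 lower of 11, led by the lipid transfer gene LTP-2; these 3 leading genes read in the dim range, so their sizes are not established. None of the lists in these last 2 groups passed camera (adjusted p = 0.322 or more). Adjusted over the list alone the counts of this paragraph and the 2 before it were the same where not given, except 1 higher and 6 lower for sugar, 0 for light harvesting, 6 lower for housekeeping, 7 lower for secondary wall, 3 lower for root and 7 lower for epidermis genes. Small list medians turn with scaling, from 0.03 to -0.06 or below for other starch breakdown and from 0.02 to -0.05 or below for trehalose synthesis, and those of light harvesting, clock and defence genes cross 0 as well. Fitted with line as a block, limma called more in several lists: 3 higher and 1 lower for starch synthesis, 6 and 4 for TIFY, 5 and 6 for phenylpropanoid, 2 and 1 for light harvesting, 2 and 4 for peroxide and glutathione, 2 and 2 for defence, 1 and 8 for dividing cell, 0 and 4 for root, 0 and 11 for housekeeping and 3 and 9 for sugar genes.

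Over all probe sets limma called 5119 higher and 6925 lower after cold. The split was 3769 and 8210 on the values as deposited and 3208 and 8648 with arrays centred on their medians, while 956 calls were at least 2-fold, 626 higher and 330 lower. No array was taken at 6 h without cold, so cold and time of day were not separated.

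Within each cultivar (3 arrays against 3) the response was alike. In ZH11, DREB1B rose by 6.39 (SE 0.11) and DREB1A by at least 6.14, and in Huayang by at least 6.51 and 5.99. In each, 4 of 5 DREB1 genes were higher over all probe sets and 5 adjusted over the list alone (camera adjusted p = 8.72e-08 in ZH11 and 1.91e-07 in Huayang; adjusted p = 0.138 and 0.212 with an estimated correlation). TIFY genes had 6 higher and 2 lower of 13 in each, also adjusted over the list alone (camera adjusted p = 0.00102 and 0.000745; adjusted p = 0.629 and 0.65 with an estimated correlation), with a median of -0.04 against a mean of 1.81 in ZH11, and with line as a block 8 and 4 in Huayang. In Huayang 14 of 22 expansin genes were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.000373, and adjusted p = 0.502 with an estimated correlation). In ZH11 5 were lower and 1 higher, and the list did not pass camera. With line as a block 12 were lower in ZH11 and 14 in Huayang. Calls numbered 1945 higher and 3232 lower in ZH11 and 2414 and 4217 in Huayang; 1445 were higher and 2367 lower in both, where independent lists would share 137 and 397, and 2 were opposite. Changes correlated at r = 0.90 across probe sets. With line as a block ZH11 had 11166 calls, 4264 higher and 6902 lower, and Huayang had 9440, 3945 higher and 5495 lower. With median centring the splits were 1400 and 3899 in ZH11 and 1784 and 5066 in Huayang. Without overexpression line 28 ZH11 had 3034 calls when it was left out before cold and 2847 when it was left out at 6 h, and without the wild type arrays Huayang had 3878.

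The difference in cold response between the cultivars was tested as an interaction (3 lines against 3). TIFY11A rose by at least 5.87 in ZH11 and by 4.58 in Huayang, a difference of 1.63 (SE 0.25, adjusted p = 0.0331), or 1.29 with readings below 73.9 set to 73.9, and the glutaredoxin gene GRXS3 also passed (adjusted p = 0.0299). GRXS3 read between 21.4 and 66 on all arrays, within the range of the dim marker probe sets (up to 73.9), so the size of its difference is not established. Each side holds a control or wild type line and 2 lines altered in OsMYB30, overexpressed in ZH11 and mutated in Huayang, so the design does not part cultivar from OsMYB30 status. The control and wild type, 1 line each and part of that test, differed in the direction of the call for 35 of the 35 probe sets; TIFY11A changed by 6.66 in the control and 4.85 in the wild type. TIFY genes as a list had 1 of 13 higher, 2 with line as a block, and 3 adjusted over the list alone (camera adjusted p = 0.00758; adjusted p = 0.738 with an estimated correlation). Expansin genes had 0 of 22 called, 1 adjusted over the list alone and a median of 0.13, with values of 1.59 for EXPA7 and 1.095 for EXPA5, which reached the dim range in Huayang at 6 h (camera adjusted p = 2.9e-05; adjusted p = 0.738 with an estimated correlation). limma called 32 probe sets higher in ZH11 and 3 lower, 35 in all, and 198 with line as a block (144 and 54), all 35 included. Leaving out 1 array gave 20 calls without overexpression line 2 before cold, 13 without line 28 at 6 h, 20 without the ZH11 control at 6 h, 21 without mutant line 1 before cold, 20 and 21 without mutant line 2 before cold and at 6 h, and 15 without the wild type before cold. TIFY11A lost its call in 10 of 12 such runs and GRXS3 in 11 of 12 (adjusted p 0.0501 to 0.112).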

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

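The tests of the marker signal, of time of day and of RNA degradation were chosen after the results were seen, and so were those of the control arrays and of plants or handling; the test of scaling and the splits were not. No group held the 4 samples that a search for stray samples needs.

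A difference in cold response between the cultivars was found by the interaction test for 35 probe sets in limma, among them TIFY11A (1.63 higher in ZH11, or 1.29 with readings below 73.9 set to 73.9). GRXS3 passed too (1.02), but at intensities of 21.4 to 66, in the range of the dim marker probe sets, so that size is not established. The design does not part cultivar from overexpression against mutation of OsMYB30; the control and wild type, which carry neither, differed in the direction of the call for 35 of 35, but they are 1 line each and part of the test that chose these probe sets, so both stay open. With line as a block 198 were called, against at most 0 in the other splits of the 6 lines into 3 and 3, and 10 splits are too few for a share under 0.05. Without the control and wild type arrays 3 were called.

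One marker probe set, outside the comparisons of plant genes, read 2658.5 before cold and 3821.8 at 6 h in the wild type, above the ZH11 control at no more than 64.3. RNA of overexpression plants in the wild type samples is argued against, since the second marker probe set read at most 42.1 there, where 2163 and 2837 would be needed. RNA of the mutants or marker-bearing plants in the wild type samples stays open: 0 of 7178 probe sets of at least 500 in the mutants lay below the needed share of 16.8% and 24.08%, but 1 of 12810 of at least 200 did, a transcript with no gene at 10.1% and 9.12%, which goes against RNA of these mutant lines and, as 1 probe set found after the fact, does not settle it. A transcript of the Huayang background that binds the probe set stays open too, the wild type lying at least 59.4-fold above a ZH11 control that reads no higher than the dim marker probe sets. No biological explanation was tested.

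The overexpression lines differed from the control in 1395 probe sets as a mean of both times, with the control arrays apart on the third component. Independent error of the single control arrays is argued against by r = 0.69 across probe sets between the changes before cold and at 6 h, which share no array. The scaling between arrays is argued against as the whole cause of the 1395 calls, as 78.6% were called again with median centring. With that centring the number of lower calls fell and that of higher calls rose. The share called again was not split by direction, so for the lower calls scaling stays open. Plants or handling that set the control apart cannot be told apart from OsMYB30 overexpression, because the control is 1 line; with line as a block 425 calls were left, so either source may underlie them.

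Control probe sets for ribosomal RNA, outside the comparisons, read higher at 6 h in 6 of 6 lines, by a median of 2.87-fold for 25S, 3.21-fold for 5.8S and 1.09-fold for 18S (exact paired permutation test, two-sided, p = 0.0312 each, the smallest that 6 pairs allow). The actin 3' to 5' ratio was higher at 6 h in 1 of 6 lines, so it gave no sign of more degraded RNA after cold. It does not exclude such degradation as a source of the cold response. The ratio was high throughout, at 11.52 to 16.05 before cold and 10.06 to 12.20 at 6 h, while that of cyclophilin lay between 1.71 and 2.06. The actin 5' signal was thus weak beside the 3' signal on every array, which makes the ratio a coarse measure. Time of day stays open for the cold response, as 4 of 7 clock genes were called and no uncooled array was taken at 6 h, so part of it may follow the hour. Chance is argued against for all lines, where 12044 calls stand against at most 4 in the other splits, of 100 with the real one included. With line as a block 15772 stand against at most 0 in the others of the 32 splits that part each line's arrays. The other splits mix cooled and uncooled arrays, so few calls in them are likely. Within ZH11 (5177 calls) and Huayang (6631) the highest other split gave 0, and 10 splits are too few for a share under 0.05.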

How the results depend on the processing

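Without the control and wild type arrays, and fry with line as replicate block, were chosen after seeing the data. Of 1243 values of named genes under alternatives 1105 kept direction and side of the threshold, 1 was stronger (NAS1 with line as a block), 3 turned and the others lost their call. The 3 are RGP3, at 0.21 both as a mean of both times and at 6 h, and EXPA7, at 0.16, each with another probe set. Of the counts 193 stayed within 1.5 times and 93 did not. The cause was not tested, except that a fold minimum lowers counts by construction. For the overexpression lines before cold 196 became 320 on the values as deposited, 621 with median centring, 384 with robust eBayes and 63 at 2-fold; at 6 h 107 became 52 at 2-fold; and for the mean 1395 became 114 at 2-fold and 425 with line as a block. For the mutants before cold 1 became 2 as deposited, median-centred, without a filter, with pseudocount 1 or with line as a block, and 0 within 1 cultivar; at 6 h 7 became 13 without a filter and 11 with pseudocount 64 or within 1 cultivar; and for the mean 9 became 5 with averaged probe sets or without trend, 18 with robust eBayes and 4 with the block. Interactions with cold went from 0 to 1 with the block for both genotypes, and to 1 within 1 cultivar for overexpression. Cold in ZH11 went from 5177 to 940 at 2-fold, 11166 with the block and 8646 with 8 group means; Huayang from 6631 to 1035 at 2-fold and 3878 without the control and wild type arrays; all lines from 12044 to 956 at 2-fold; the cultivar interaction from 35 to 198 with the block and 3 without the control and wild type arrays. NAS1 gained a call with line as a block. In the overexpression mean 8 named genes and the list members PAL and DREB1G lost theirs, as LOC4348874, LOC4339518 and LOC4333966 did in the mutants. List members of the overexpression mean not named above lost theirs too: DPE1, TPP9, LIR1, SAPK9, LAC10, CIN4, CIN7 and SWEET4.

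Counts where both lines passed a fold went from 102 to 704 at 1.5-fold and 15 at 4-fold in the overexpression lines before cold, from 100 to 427 and 13 at 6 h, from 5 to 73 and 3 in the mutants before cold (8 without a filter) and from 62 to 251 and 15 at 6 h. Opposite calls in both genotypes numbered 24 at an adjusted p below 0.2 for the mean and 14 at 6 h, calls in the same direction 16 and 2, and with both lines at 2-fold there were 1 opposite before cold, and 9 opposite and 2 alike at 6 h. Lists past the threshold fell to 0 with an estimated correlation in camera in each contrast that had any, save 1 for cold in all lines. In fry they were 3 and 3 for overexpression before cold and at 6 h, 3 and 4 with line as replicate block and 4 for the mean with it; 0 for the mutants before cold, with the block too; 0 for the mutant and cultivar interactions; and 5, 14 and 16 for cold in ZH11, Huayang and all lines. As deposited, the mutants had 6 lists before cold, 4 at 6 h and 4 for the mean.

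With 1 array left out, calls ranged from 60 to 123 for overexpression before cold, 35 to 40 at 6 h and 309 to 1442 for the mean; 3 to 3, 5 to 84 and 4 to 30 for the mutants; 0 to 0 and 0 to 1 for the interactions; 2847 to 7088 in ZH11, 4507 to 6114 in Huayang, 10116 to 12763 in all lines and 13 to 51 for the cultivar interaction. NAAT1 lost its call as deposited (adjusted p 0.0719 in limma), with median centring (0.0656), the 60th percentile filter (0.0546), no trend (0.0687) and within 1 cultivar (0.0677). GRXS3 has no value under the 60th percentile filter, and list definitions by keyword alone or by ID alone were not run. Dim probe sets near the background are the least precise.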

Other observations

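Of 64 marker probe sets, 62 read at most 73.9 on any array, with a median of 9.3. MYBS3, which carries the alias myb30 in the annotation and was not taken as the target, had a change of 0.00 (SE 0.07) in the overexpression lines as a mean of both times.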
